A study of Rattus norvegicus with 9 samples.

How the data were processed

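Kidney RNA was measured by RNA sequencing in 9 libraries, in 3 groups of 3: Wistar-Kyoto rats (WKY, a normotensive strain), spontaneously hypertensive rats (SHR, an inbred strain derived from Wistar-Kyoto stock that develops high blood pressure), and SHR given dapagliflozin. Dapagliflozin inhibits the sodium-glucose cotransporter SGLT2, which recovers filtered glucose in the early proximal tubule. Per the labels' protocols, rats entered the study at 3 months of age, dapagliflozin was given by mouth at 10 mg/kg per day for 8 weeks, and both untreated groups received distilled water. Another label field gives saline as the control treatment, and the strain field reads Wistar-Kyoto for every sample, so groups were taken from the sample titles. The labels name 3 rats per group and 3 libraries per group but do not tie each library to an animal, and p-values therefore measure the spread between these libraries.

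Per the labels' protocols, total RNA was extracted with Trizol and libraries were sequenced as single-end 50-base reads on a BGISEQ-500 instrument. Per the submitters' processing notes, HISAT2 2.0.4 and Bowtie2 2.2.5 were used with the rat build Rnor_6.0, and the role of each tool is not stated there. The program that computed expression, the gene annotation and any filter applied before deposit are not given in the sources used here. Per the file headers, the deposited values are FPKM (fragments per kilobase of transcript, scaled to each library's mapped reads) as computed by the authors, 1 column per library, rounded to 2 decimals. Because of that scaling, a large change in a few abundant transcripts lowers or raises all others, and transcripts with near-identical copies can exchange reads.

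The table held 19367 genes, 8 of them with a symbol that occurs more than once. Gene IDs were matched to a reference table of the GRCr8 assembly, which was used only for names and for which genes neighbour each other, because its build differs from the authors' build. Of the IDs, 17897 matched and 16411 of these had the same symbol. Genes with an FPKM of at least 1 in at least 3 of the 9 libraries were kept, which left 13127 genes, 12608 of them matched. Values were analysed as log2(FPKM + 1) with a pseudocount of 1, so fold changes are on that scale and understate the change of weakly expressed genes.

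The 3 contrasts (SHR against WKY, treated SHR against SHR, treated SHR against WKY) were tested with limma 3.58.1 in R 4.3.3, using a group-means model of all 9 libraries with 6 residual degrees of freedom, an intensity trend in the variance prior and Benjamini-Hochberg adjustment over all genes kept. Tests were two-sided and a gene was called at an adjusted p of 0.05. Gene lists, 36 in all, were fixed before the data were examined; they cover nephron segments, other kidney cell types, blood pressure systems, metabolism, stress, immunity and genes named in earlier work on hypertensive rats. Lists with at least 5 kept genes, 32 in all, were tested against the other genes with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation was an alternative. Fry, also run, asks whether the members of a list changed at all and not whether they differ from other genes, so its calls answer another question. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for exact permutation tests and plots.

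Genes named in the text follow a rule that was also fixed before the data were examined. It takes the 10 largest rises and the 10 largest falls among called genes with a mean FPKM of at least 5 in the higher group, non-overlapping groups and a proper symbol, then up to 4 called members of each list by smallest p, and in every contrast a fixed set that includes Slc5a2, Slc5a1, Agt, Ace, Havcr1, Lcn2, Tgfb1 and Col1a1. Some genes that the rule takes are not reported here by name, and list results and counts include them. Where fewer than 10 genes pass, it takes the 5 higher and 5 lower genes with the smallest unadjusted p and says that they did not pass. Placeholder symbols left out were those starting with LOC, RGD, AABR, ENSRNOG, MGC or numbers. The AC prefix was applied as AC followed by digits, since gene symbols such as Acsm3 share it, and NEWGENE symbols were treated as placeholders.

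The test was run on simulated data with the real genes, means and spread, in which genes varied independently of each other. Among genes with a mean log2(FPKM + 1) above 2, 100 were changed by a log2 change of 1 and 100 by 2. Recovery of more weakly expressed genes was therefore not tested. For SHR against WKY the test recovered 87 and 95 of the changed genes with 13 false calls. For treated SHR against SHR it recovered 83 and 94 with 8 false calls, and for treated SHR against WKY 80 and 96 with 8 false calls. Camera called a simulated list of 20 genes shifted by 0.5 and 0 of 29 unshifted lists; in that simulation genes varied independently of each other, which kidney transcripts do not.

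FPKM values carry no read totals, so absolute depth is unknown and no interval for counting error is given. The steps between low values gave a rough relative depth per library, between 0.934 and 1.072 over 5 settings, with errors of 4.9 to 22.2% in a simulated test, so no difference in depth between libraries can be read from them. Alternatives tried were a replicate block, pseudocounts of 0.1 and 0.5, no filter and a stricter filter, median-of-ratios and quantile scaling, limma without a trend, array weights, only the libraries of the compared groups, a 2-fold minimum, and each library left out in turn. A covariate for nephron segment was added after the data were examined: the mean of a late proximal list written then, minus the mean of the podocyte list, which is also one of the lists tested. No sample and no column of values was left out of the table.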

Results

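Gene expression was measured by RNA sequencing in kidney tissue from 3 WKY, 3 untreated SHR and 3 dapagliflozin-treated SHR libraries. Expression was available as FPKM for 19367 genes, and 13127 genes were expressed well enough to be tested. The FPKM sums lay between 563643 and 589838 per library, and read totals are unknown. On the log2 scale, library pairs of the same group correlated at 0.970 to 0.989 (Pearson's r across genes, which are not independent replicates), and pairs from different groups at 0.922 to 0.988. Of the Y-linked transcripts, Eif2s3y was present at 36.1 to 45.4 FPKM and Kdm5d at 5.26 to 6.19 in all 9 libraries. Uty lay at 0.42 to 1.16, Ddx3y and Usp9y at no more than 0.15 and 0.03, and Sry at 0.

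The first principal component held 53.0% of the variance. WKY libraries scored between -42.3 and -16.6 on it, untreated SHR between -1.76 and 10.1, and treated SHR at 4.71, 31.6 and 42.5. Treated library 1 therefore lay within the range of the untreated SHR libraries on this component, and treated libraries 2 and 3 lay outside it. The segment score, the late proximal minus the podocyte list mean, used a list written after the data were examined. It was 4.709, 2.5 and 3.957 in WKY libraries 1 to 3, and 1.838 to 2.909 in untreated SHR. Treated libraries 1 to 3 had 2.918, 0.41 and 0.55. Libraries low on the component mostly had high scores, also within WKY, so it does not separate group from nephron segment.

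**Figure D1:**
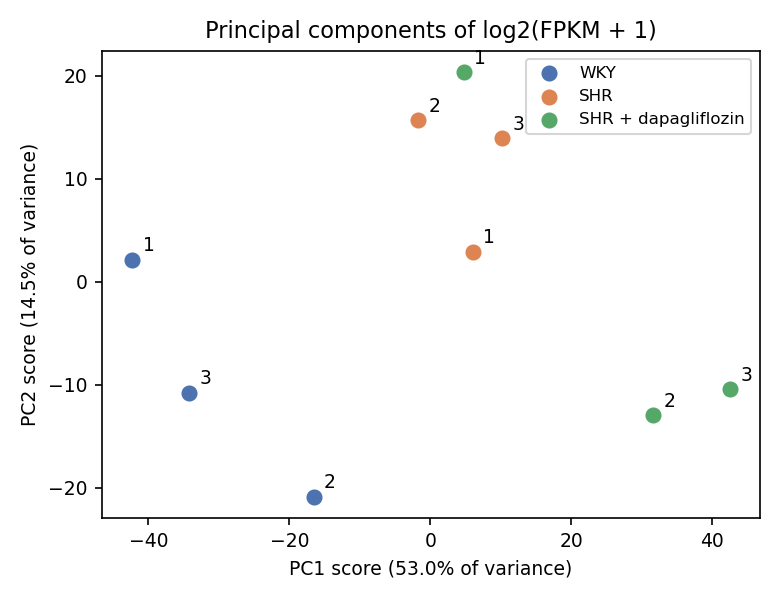
Scores of the 9 libraries on the first (x axis, 53.0% of variance) and second (y axis, 14.5% of variance) principal components of log2(FPKM + 1). Each point is 1 library, numbered by replicate and coloured by group; WKY libraries lie left of every SHR library, and treated library 1 lies near the untreated SHR libraries.

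The comparison of untreated SHR with WKY asked how the kidney of the hypertensive strain differs from that of its normotensive control. The kidneys of SHR carried far more transcript of Ephx2 (gene ID 65030), the soluble epoxide hydrolase that inactivates vasodilator epoxides of arachidonic acid, at 56.6 ± 6.13 FPKM against 4.84 ± 1.09 in WKY (mean ± SD, n = 3 per group). Acsm3, a medium-chain acyl-CoA synthetase encoded at the SA locus long studied in hypertensive rats, stood at 1001 ± 201 against 53.4 ± 17.4 FPKM. Cd36, the fatty acid translocase, fell to 1.41 ± 0.679 from 9.41 ± 2.85 FPKM, and Dapk2, a calcium/calmodulin-dependent protein kinase, fell to 1.69 ± 0.0586 from 20.9 ± 2.70 FPKM. Aqp3, a basolateral water channel of the collecting duct, rose to 136 ± 1.03 from 45.8 ± 12.3 FPKM.

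In limma with Benjamini-Hochberg adjustment, 388 genes differed between the strains, 241 higher and 147 lower in SHR, and 171 of them by at least 2-fold. The log2 change of Ephx2 was 3.31 (SE 0.19, adjusted p = 3.34e-05), that of Acsm3 4.24 (SE 0.30, adjusted p = 0.000123), that of Cd36 -2.12 (SE 0.24, adjusted p = 0.00262), that of Dapk2 -3.02 (SE 0.11, adjusted p = 2.45e-06) and that of Aqp3 1.58 (SE 0.22, adjusted p = 0.006). Groups did not overlap for any of the 388 genes, nor for 28.4% of all genes tested, where chance gives 10%. With quantile normalization 407 genes were called, of which 49.6% were higher in SHR, against 62.1% as deposited, so the balance of rises and falls depends on the scaling. The count was 196 without WKY library 1, 167 without WKY 3, 170 without SHR 1, 191 without SHR 2, 212 without SHR 3 and 626 without treated library 1. Under the nephron segment covariate, added after the data were examined, 348 genes were called, and 252 of the 388 kept their call. All 388 kept their sign, and their median log2 change, taken in its direction before, went from 0.907 to 0.821. Part of any group difference is removed with that covariate.

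Among other large rises in SHR, Fmo2, a flavin-containing monooxygenase, rose to 41.8 ± 2.81 from 6.23 ± 2.46 FPKM. Cyp8b1, the sterol 12-alpha-hydroxylase of bile acid synthesis, stood at 18.8 ± 9.29 against 0.807 ± 0.115 FPKM, and this call was lost when WKY 1, WKY 2, WKY 3, SHR 1 or SHR 2 was left out. Apoh, a phospholipid-binding plasma glycoprotein, was listed at 0 in all 3 WKY libraries and at 7.21, 12.2 and 9.50 FPKM in SHR. Setd4, a methyltransferase gene, was listed at 0.05, 0 and 0.01 FPKM in WKY and at 6.22, 5.35 and 6.71 in SHR. Among the falls, Pigz, a mannosyltransferase of GPI anchor synthesis, dropped to 3.35 ± 1.34 from 36.7 ± 6.37 FPKM, Dnm1, a dynamin of endocytosis, to 1.52 ± 0.132 from 17.1 ± 4.71, Timd2 to 4.35 ± 0.604 from 35.9 ± 7.21, and Tmed6 to 8.38 ± 2.12 from 70.0 ± 19.8.

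Several strain differences lay in genes whose reads can be shared with near-identical copies or overlapping genes, and these are uncertain. Ndufa10l1 was listed at 0.29, 0 and 0 FPKM in WKY and at 40.0, 35.3 and 32.2 in SHR, while its parent gene Ndufa10, a subunit of respiratory complex I, stood at 97.1 ± 5.45 in SHR against 131 ± 8.79 in WKY. Eri2, which overlaps Acsm3, stood at 114 ± 26.4 against 9.30 ± 2.21 FPKM. Cbr1, a carbonyl reductase with close copies nearby, was listed at 0 in the 3 WKY libraries and at 8.94, 9.84 and 10.8 in SHR. Class I histocompatibility genes moved in both directions, with RT1-A1 at 389 ± 24.1 against 86.1 ± 9.26 FPKM and RT1-CE10 at 10.6 ± 1.88 against 70.2 ± 2.88. RT1-CE2 stood at 40.2 ± 3.61 against 3.48 ± 0.665 FPKM and RT1-N2 at 2.53 ± 0.513 against 31.4 ± 3.36. Gstm1, a glutathione transferase of a gene cluster, stood at 34.8 ± 4.21 against 247 ± 78.5 FPKM, and the olfactory receptor Olr1668 at 0.320 ± 0.171 against 8.98 ± 5.67. Hba-a3, an alpha globin, was listed at 22.2, 29.1 and 44.7 FPKM in WKY and at 0.49, 0 and 0.24 in SHR, and the histone gene H2bc12 at 10.2, 10.3 and 11.1 in WKY and at 0 in each SHR library.

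Transporters and markers of the nephron segments moved by less than these single genes but mostly in a common direction within each list. Of 24 proximal tubule genes, 18 had lower and 6 higher mean levels in SHR. Slc9a3, the apical sodium-proton exchanger NHE3, rose to 39.7 ± 4.33 from 24.96 ± 1.86 FPKM (log2 change 0.65, SE 0.11, adjusted p = 0.015) and was the only member called over all genes. Adjusted over the list alone, 1 member was higher and 1 lower. Of 28 distal salt transport genes, 25 had higher levels, and Fxyd4, a regulator of the sodium pump, passed at 45.8 ± 12.2 against 21.2 ± 3.31 FPKM, as it did adjusted over the list alone. Of 16 collecting duct genes, Aqp3 and the vasopressin receptor gene Avpr1a (7.06 ± 1.26 against 3.65 ± 0.296 FPKM) rose, and 9 rose and 1 fell adjusted over the list alone. None of 13 intercalated cell genes passed over all genes, and 7 were higher adjusted over the list alone. All 12 podocyte markers had higher means in SHR and 0 passed. A different mix of kidney regions in the tissue pieces was not separated from strain for these lists.

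Camera placed the proximal tubule list lower than other genes (adjusted p = 0.00834, and adjusted p = 0.806 with an estimated correlation), with a median log2 change of -0.39. The distal salt transport list was higher (adjusted p = 0.0203, and adjusted p = 0.860 with an estimated correlation). The collecting duct (adjusted p = 0.0104), intercalated (0.00834), inner medulla (0.0419) and podocyte lists (0.00455) were also higher, each at an adjusted p of 0.806 with an estimated correlation. Glucose carriers were lower (adjusted p = 0.0437, and adjusted p = 0.806 with an estimated correlation), with 0 of 13 members called over all genes or adjusted over the list alone. Of 32 lists tested, 14 were called by camera, 8 higher and 6 lower, and 0 were called with an estimated correlation or by fry. With median-of-ratios scaling 8 were higher and 3 lower, and with quantile normalization 8 and 2; the calls of the proximal tubule and glucose carrier lists were lost under both. Without WKY 1 the number of lists called was 6, and without SHR 3 it was 9. In 1 of the 9 other splits of these 6 libraries as many lists were called, so list calls are weak evidence here.

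In lipid and sterol metabolism few members of each list passed. Of 41 fatty acid oxidation genes, Cd36 and Cpt1b, the muscle-type carnitine palmitoyltransferase (5.61 ± 0.176 against 10.6 ± 1.54 FPKM), fell, 39 did not pass, and the same 2 fell adjusted over the list alone. The list was lower by camera (adjusted p = 0.00834, and adjusted p = 0.806 with an estimated correlation), at a median log2 change of -0.05. In cholesterol synthesis Lss, lanosterol synthase (4.96 ± 0.07 against 9.19 ± 0.504 FPKM), and Sqle, squalene epoxidase (7.63 ± 0.409 against 11.2 ± 0.285), fell, 23 of 25 members did not pass, and 3 fell adjusted over the list alone; the list was not called (adjusted p = 0.881 by camera). Of 31 arachidonic acid genes, Ephx2, the secreted phospholipase Pla2g2a (5.11 ± 1.95 against 0.640 ± 0.437 FPKM) and the cyclooxygenase Ptgs1 (6.19 ± 0.407 against 3.02 ± 0.577) rose, and 3 rose and 1 fell adjusted over the list alone, while the list as a whole was not called (adjusted p = 0.720).

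Of 17 genes named in earlier work on hypertensive rat strains, Ephx2 and Acsm3 rose and Gstm1, Endog and Cd36 fell, with the same 2 and 3 adjusted over the list alone, and the list was not called (adjusted p = 0.544 by camera). Of 23 unfolded protein and heat shock genes only Xbp1, a transcription factor of that response, passed (108 ± 7.7 against 80.3 ± 4.14 FPKM), 4 rose adjusted over the list alone, and the list was not called (adjusted p = 0.196).

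Immune and vascular genes were mixed. Il18, an inflammasome cytokine, rose to 24.5 ± 10.1 from 5.17 ± 2.24 FPKM and was the only 1 of 28 inflammation genes to pass. In the interferon list Ifit1 was listed at 0, 0.04 and 0 FPKM in WKY and at 6.45, 3.22 and 3.55 in SHR, while Ifi44l (1.22 ± 0.441 against 4.74 ± 0.660) and Parp14 (5.60 ± 0.533 against 8.79 ± 0.863) fell and 34 of 37 members did not pass. That list was lower by camera (adjusted p = 0.000498, and adjusted p = 0.806 with an estimated correlation), as was antigen presentation (0.0103, and 0.860 as the adjusted p with an estimated correlation). The groups overlapped in both list means. On the log2 scale the interferon list mean was 2.526, 3.057 and 3.037 in WKY and 3.012, 2.528 and 2.485 in SHR. Clu, the chaperone clusterin, fell to 44.2 ± 3.14 from 105 ± 13.0 FPKM, Vwf, von Willebrand factor of endothelial cells, to 2.19 ± 0.211 from 9.19 ± 2.42, and Endog, a mitochondrial endonuclease, to 10.6 ± 1.52 from 26.8 ± 2.36. Vwf was the only 1 of 13 endothelial genes with a lower mean log2 level in SHR, and the other 12 were higher. The bradykinin receptor gene Bdkrb2 rose to 2.29 ± 0.281 from 0.503 ± 0.142 FPKM, and the stress-induced Ddit4 to 19.6 ± 5.17 from 7.66 ± 1.34. Of the 50 named genes called, 32 kept their call whichever library was left out, and Slc9a3, Fxyd4, Avpr1a, Cpt1b, Sqle, Ptgs1, Parp14, Vwf, Ddit4, Ndufa10 and RT1-A2 were among those that did not.

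**Figure D2:**
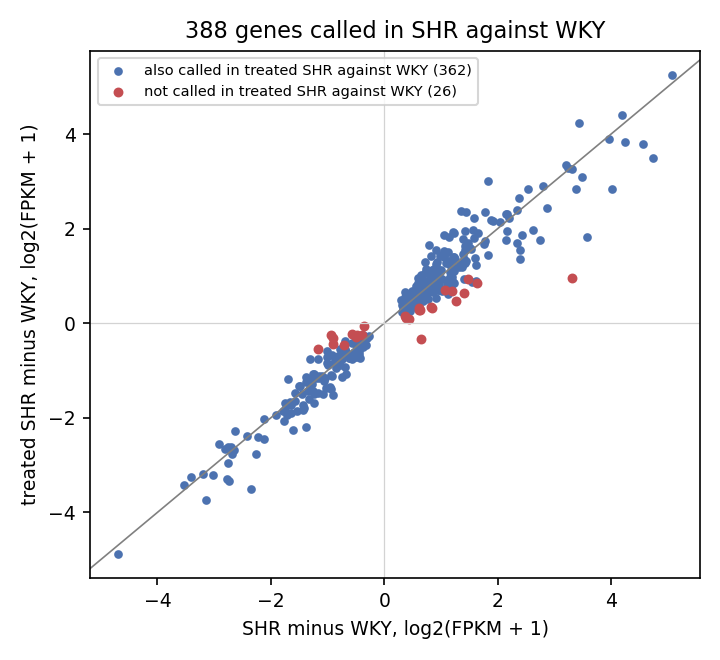
Log2(FPKM + 1) differences of the 388 genes called in SHR against WKY: untreated SHR minus WKY on the x axis and treated SHR minus WKY on the y axis, 1 point per gene, with the line of equal values. The 362 genes also called in treated SHR against WKY are blue, the other 26 are red, and points lie near the line.

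The comparison of treated with untreated SHR asked what 8 weeks of dapagliflozin changed in the kidney of the hypertensive strain. No single gene passed in the main fit. Slc9a3 (gene ID 24784), the sodium-proton exchanger NHE3 of the proximal tubule and thick limb, had the smallest p and measured 19.7 ± 1.98 FPKM in treated SHR against 39.7 ± 4.33 in untreated SHR (n = 3 each), a level below the 24.96 ± 1.86 FPKM of WKY. Aqp4, a basolateral water channel of the collecting duct, measured 38.1 ± 11.6 against 11.7 ± 2.46 FPKM. All 24 proximal tubule genes had lower means in treated SHR, 25 of 28 distal salt transport genes had higher means, and all 13 intercalated cell genes had higher means. Treated libraries differed in which proximal genes were low, by 2 lists written after the data were examined. Treated library 1 had a late proximal mean of 7.145 on the log2 scale, above all untreated SHR (6.62 to 7.105). Treated library 2 had an early proximal mean of 6.1, within their range (5.461 to 6.581). The other list of each, and both in treated library 3, lay below all untreated SHR.

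In limma with Benjamini-Hochberg adjustment 0 of 13127 genes were called, and the smallest adjusted p was 0.117, for Slc9a3 (log2 change -0.97, SE 0.11). At an unadjusted p under 0.05 there were 1997 genes, 1289 higher and 708 lower, and groups did not overlap for 19.0% of genes. Without treated library 1, 830 genes were called, 407 higher and 423 lower, and all 10 genes named here by smallest p were among them, as was Agt. That fit rests on treated libraries 2 and 3, whose late proximal means (5.07 and 5.464) lay below those of all untreated SHR (6.62 to 7.105). With a replicate block, Slc9a3 was called (adjusted p = 0.0341), although the replicate numbers do not pair the libraries. Limma with array weights called 3590 genes, but it also called genes in 22 of 60 fits to libraries regrouped so that each set held 1 library of each group, where limma without weights did so in 1 of 60. In such sets group differences enter the spread within sets, so these fits do not show how often either method errs under the real grouping.

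The other genes with the smallest p did not pass (adjusted p = 0.281 each, limma with Benjamini-Hochberg adjustment). Higher in treated SHR were Cds1, a CDP-diacylglycerol synthase (35.7 ± 5.26 against 21.9 ± 1.18 FPKM), Efna1, an ephrin (24.3 ± 1.46 against 17.4 ± 1.42), the transcription factor gene Glis3 (16.4 ± 1.32 against 11.6 ± 0.331) and Avpr1a (13.9 ± 3.11 against 7.06 ± 1.26). Lower were Ankrd33b (6.21 ± 0.451 against 9.28 ± 0.331), Sap18 (12.8 ± 1.64 against 21.4 ± 2.2), the histone methyltransferase gene Kmt5a (32.6 ± 1.49 against 41.7 ± 0.433) and Lyrm4, a partner in iron-sulphur cluster assembly (23.5 ± 1.18 against 31.3 ± 1.17).

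The drug's target transcript, Slc5a2 (gene ID 64522), varied widely within every group. It measured 9.75, 70.3 and 43.5 FPKM in WKY, 42.9, 23.7 and 2.69 in untreated SHR and 0.63, 20.8 and 8.35 in treated SHR, and the difference between treated and untreated SHR did not pass (log2 change -1.20, SE 1.18, adjusted p = 0.637 in limma). Slc5a1, the glucose carrier SGLT1 of the late proximal tubule, measured 9.94 ± 4.04 in treated against 10.4 ± 0.386 in untreated SHR (adjusted p = 0.846). Of the angiotensin genes, Agt measured 30.5 ± 26.5 against 40.1 ± 10.3 FPKM (adjusted p = 0.522), at 60.7, 11.2 and 19.4 in the 3 treated libraries, and was called lower without treated library 1 (log2 change -1.35, adjusted p = 0.0399). That call rests on treated libraries 2 and 3, which were low in late proximal genes. Ace measured 1.04 ± 0.239 against 1.05 ± 0.160 (adjusted p = 0.991). The injury marker Havcr1 (KIM-1) measured 0.133 ± 0.0451 against 0.847 ± 0.621 FPKM and Lcn2 (NGAL) 4.69 ± 1.86 against 5.48 ± 0.529. The fibrosis genes Tgfb1 (15.4 ± 4.17 against 13.9 ± 2.64) and Col1a1 (4.22 ± 1.03 against 3.64 ± 1.15) differed by less than their spread.

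**Figure D3:**
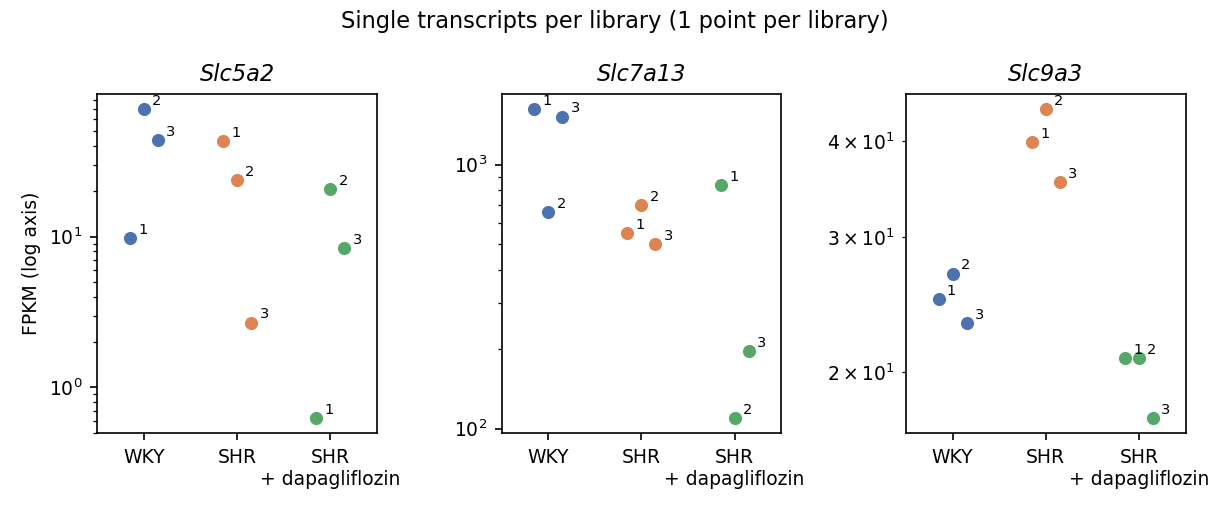
FPKM on a log axis for Slc5a2, Slc7a13 and Slc9a3 in each of the 9 libraries, 1 numbered point per library. Slc5a2 spans 0.63 to 70.3 FPKM and overlaps between groups, while the 3 treated SHR libraries lie at 17.4 to 20.9 FPKM for Slc9a3, below all untreated libraries.

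As lists, the proximal tubule genes were lower in treated than in untreated SHR by camera (adjusted p = 9.25e-10, and adjusted p = 0.751 with an estimated correlation), with a median log2 change of -0.72. The list mean on the log2 scale was 6.52 ± 0.41 against 7.25 ± 0.15 (SD, n = 3; two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows). Adjusted over the list alone, 1 member, Slc9a3, was lower. Distal salt transport genes were higher (adjusted p = 1.82e-06, and adjusted p = 0.865 with an estimated correlation), with list means of 7.21 ± 0.31 and 6.75 ± 0.03 (exact permutation p = 0.1) and 0 members passing adjusted over the list alone. Intercalated cell genes were higher (adjusted p = 1.82e-06, and adjusted p = 0.751 with an estimated correlation), with list means of 7.60 ± 0.36 and 6.99 ± 0.28 (exact permutation p = 0.2) and 9 of 13 members higher adjusted over the list alone. The podocyte list was not called (camera adjusted p = 0.834), at 4.60 ± 0.35 against 4.49 ± 0.29 (exact permutation p = 0.7).

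Of the other lists, glucose carriers (adjusted p = 0.00751, 11 of 13 members lower) and glutathione and redox genes (adjusted p = 0.00721, 28 of 41 lower) were lower by camera, both at an adjusted p of 0.751 with an estimated correlation. Respiratory chain subunits (adjusted p = 0.0203, 37 of 44 higher, adjusted p = 0.988 with an estimated correlation) and cholesterol synthesis genes (adjusted p = 0.0287, 21 of 25 higher, adjusted p = 0.751 with an estimated correlation) were higher, at median log2 changes of 0.11 and 0.12. In these 4 lists 0 members passed over all genes or adjusted over the list alone. Of 32 lists, 7 were called and 0 held with an estimated correlation or by fry. Other splits of these 6 libraries called between 4 and 13 lists, and 8 of 9 called as many as the real one, so these list calls do not set the treated libraries apart. The calls of glucose carriers (without treated 2), redox genes (without treated 3), respiratory subunits (without SHR 3 or treated 2) and sterol genes (without SHR 3 or treated 1) were lost when a library was left out.

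**Figure D4:**
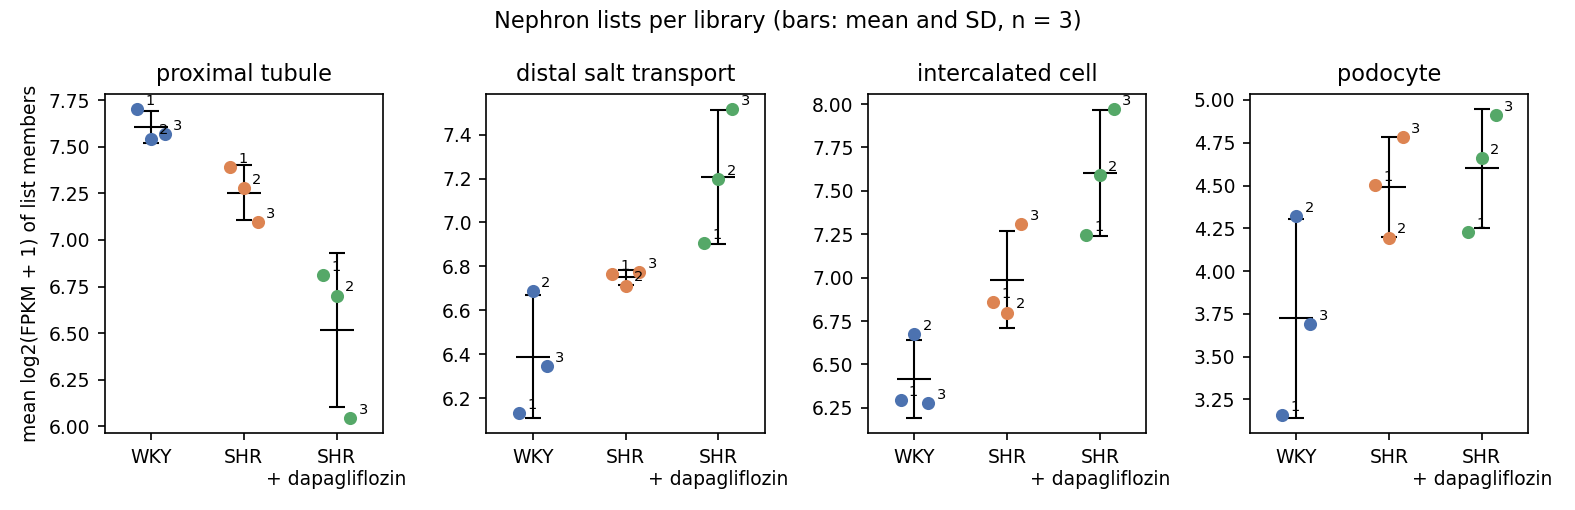
Mean log2(FPKM + 1) over the members of the proximal tubule, distal salt transport, intercalated cell and podocyte lists in each library (numbered points), with group mean and SD (bars, n = 3). Proximal means are 7.61 in WKY, 7.25 in SHR and 6.52 in treated SHR, and distal means are 6.39, 6.75 and 7.21.

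Whether dapagliflozin returned strain differences toward WKY was asked by following the 388 genes that differed between the strains. Ephx2 measured 55.5 ± 13.9 FPKM in treated SHR, Acsm3 774 ± 256 and Cd36 0.867 ± 0.110, all still far from WKY. Other strain genes moved toward WKY levels without passing in the main fit. Fmo2 measured 31.06, 31.85 and 17.93 FPKM in treated against 43.06, 38.59 and 43.77 in untreated SHR. Cyp8b1 measured 9.87, 0.73 and 1.24 against 23.08, 25.25 and 8.19. As 0 genes passed for treatment, 0 could count as reversed (called by limma in both contrasts with opposite signs), so that count does not answer the question; it was 26 without treated library 1 and 1, Slc9a3, with a replicate block. Of the 388 genes, 190 (49.0%) had the opposite and 198 the same sign in treated against untreated SHR. In 1000 simulated sets without change, 82.5% of as many genes of smallest p had opposite signs on average, with a 95% range of 12.4 to 100%. Those sets held no strain difference, while the 388 genes had a median absolute log2 change of 0.907 against a median SE of 0.142. The simulated share is therefore no chance value for these genes. Because untreated SHR enter both contrasts, chance alone gives a negative correlation of the log2 changes, -0.456 on average in the simulated sets (95% range -0.93 to 0.454), where the observed value across genes was 0.133. The covariance of 0.0143 lay just above its simulated range (-0.0781 to 0.0129, mean -0.0207). A positive value points away from a return toward WKY. The simulated sets held no strain difference, and strain differences add to the spread of the observed log2 changes. The simulated correlation is therefore not on the scale of the observed correlation, and neither range settles whether the observed value is beyond chance.

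The comparison of treated SHR with WKY combined strain and drug. Water and salt channels of the distal nephron were among the genes that rose: Aqp2, the vasopressin-regulated water channel, to 890 ± 271 from 285 ± 97.0 FPKM (n = 3 each), Aqp3 to 218 ± 58.2 from 45.8 ± 12.3, and the epithelial sodium channel subunits Scnn1b to 215 ± 59.8 from 66.2 ± 20.3 and Scnn1g to 104 ± 32.5 from 30.6 ± 9.44. Of the proximal tubule list 5 of 24 genes passed, all lower, among them the organic anion transporter gene Slc17a3 at 72.03 ± 33.9 against 227 ± 31.8 FPKM. The amino acid transporter gene Slc7a12 fell to 36.1 ± 43.5 from 221 ± 94.0. Crabp1, a retinoic acid binding protein, rose to 8.98 ± 3.71 from 0.190 ± 0.0608, and the elastase gene Cela1 fell to 4.90 ± 3.75 from 58.0 ± 1.93.

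In limma with Benjamini-Hochberg adjustment 3010 genes were called, 2211 higher and 799 lower, with 594 at 2-fold or more. The share of higher calls, 73.5% as deposited, was 53.6% with median-of-ratios scaling (2695 calls) and 59.9% with quantile normalization (2638 calls). The median log2 change over all genes moved from 0.11 to -0.01 under median-of-ratios scaling, so a change should be read relative to that shift. The count was 806 without WKY 1, 593 without WKY 3, 1076 without treated 2, 945 without treated 3 and 4791 without treated 1, and 1026 when only these 6 libraries were fitted. With a covariate for nephron segment, added after the data were examined, it was 193, and the median log2 change of the 3010 genes, taken in its direction before, went from 0.61 to 0.32 while the median SE went from 0.141 to 0.154. The covariate is made of segment markers whose mean levels differ between these groups, so part of any group difference is removed with it.

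Of the 388 strain genes, 362 were also called here, 225 higher and 137 lower in both contrasts and 0 in opposite directions. Independent lists of these sizes would share 40.6 and 8.95 genes, but these lists share the WKY libraries and are not independent. Simulated unchanged groups sharing the WKY libraries had a median of 0, which was nearly fixed in advance because genes are rarely called without change. Neither value therefore tells how many of the 362 the shared libraries alone would give. The log2 changes of both contrasts correlated across genes at 0.825, within the range that the shared WKY libraries give without change (simulated mean 0.461, 95% range -0.423 to 0.935), while the covariance of 0.156 lay above its simulated range (-0.0109 to 0.0774). A further 2648 genes were called only in this contrast, and 2600 of them (98.2%) had the same sign in untreated SHR against WKY. Simulated sets without change gave a 95% range of 23.1 to 100% for as many genes of smallest p. Those sets held no group differences, unlike these data, so that range is no chance value for this share. Whether the contrasts differ for these genes is the treated against untreated comparison, in which 0 genes passed.

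By list, 19 of 28 distal salt transport genes rose (22 adjusted over the list alone), with the smallest p for Fxyd4 (57.4 ± 8.24 against 21.2 ± 3.31 FPKM) and Nedd4l, a ubiquitin ligase of the sodium channel (40.8 ± 4.22 against 26.3 ± 0.675). Of 13 intercalated cell genes 12 rose (12 adjusted over the list alone), including Slc4a9, a basolateral anion exchanger (165 ± 47.0 against 50.9 ± 10.8), Slc26a4, the apical chloride-bicarbonate exchanger pendrin (217 ± 55.6 against 78.0 ± 18.7), and Rhcg, an ammonia channel (448 ± 136 against 146 ± 40.2). Of 16 collecting duct genes 10 rose and 1 fell (11 and 1 adjusted over the list alone), among them Gata3 (58.5 ± 17.2 against 22.1 ± 4.15). Of 24 proximal tubule genes 5 fell (15 adjusted over the list alone), including Slc27a2, a fatty acid transport protein (118 ± 50.1 against 248 ± 28.2), and Cubn, the endocytic receptor cubilin (10.8 ± 5.56 against 32.0 ± 13.3). Of 13 glucose carriers 3 fell (7 fell and 1 rose adjusted over the list alone), including Slc2a2, the basolateral carrier GLUT2 (14.4 ± 4.4 against 23.9 ± 1.58). In the angiotensin and aldosterone list, Nr3c2, the mineralocorticoid receptor gene (18.5 ± 3.95 against 8.46 ± 1.07), and Hsd11b2, the enzyme that shields it from glucocorticoids (1279 ± 411 against 424 ± 167), rose together with Agtr1b, an angiotensin receptor gene (3.05 ± 0.594 against 1.52 ± 0.306), and 12 of 15 members did not pass (3 rose adjusted over the list alone). The counts of proximal tubule, glucose carrier and angiotensin genes called were near the share over all genes, 3010 of 13127, of which 799 were lower.

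Camera called the proximal tubule (adjusted p = 7.08e-10, and adjusted p = 0.883 with an estimated correlation), glucose carrier (0.00153, and adjusted p = 0.883 with an estimated correlation) and redox lists (0.00153, and adjusted p = 0.883 with an estimated correlation) lower. The distal (4.67e-05), intercalated (4.40e-05), collecting duct (0.0136) and podocyte (0.0136) lists were higher, each at an adjusted p of 0.902 with an estimated correlation, and fatty acid oxidation was lower (0.0136, and adjusted p = 0.902 with an estimated correlation). Fry, which does not compare a list with other genes, called 10 lists, 4 of them among these 8. Other splits of the 6 libraries called 3 to 16 lists, and 6 of 9 called as many. Of the 117 named genes called, 58 kept their call whichever library was left out, and the calls of Slc2a2, Cubn, Slc27a2, Slc7a12 and Hsd11b2 were lost without WKY 3.

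Havcr1 fell (0.133 ± 0.0451 against 2.41 ± 1.54 FPKM, adjusted p = 0.028 in limma) and Col1a1 rose (4.22 ± 1.03 against 1.5 ± 0.318, adjusted p = 0.0159) in treated SHR against WKY, and both calls were lost without WKY 3 or treated 2, that of Havcr1 also without WKY 1 or treated 3. In untreated SHR against WKY neither passed, with Havcr1 at 0.847 ± 0.621 FPKM (adjusted p = 0.267) and Col1a1 at 3.64 ± 1.15 (adjusted p = 0.079). Slc5a2, Slc5a1, Agt, Ace, Lcn2 and Tgfb1 passed in neither contrast against WKY; in treated SHR against WKY, Slc5a1 and Agt passed without treated library 1, and Ace without WKY 2, all lower. Among redox genes, Sod3, extracellular superoxide dismutase, fell to 100.4 ± 28.3 from 369 ± 81.9 FPKM and Srxn1, sulfiredoxin, rose to 22.9 ± 3.76 from 7.84 ± 0.956, with 4 of 41 members higher and 5 lower (4 and 6 adjusted over the list alone). That share of members called was near the share over all genes (3010 of 13127).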

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

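The covariate for nephron segment was chosen after the data were examined, and the other alternatives before. The number of genes called in SHR against WKY was 3911 with array weights and 171 at 2-fold or more, and for treated SHR against WKY it was 8811 with array weights, 594 at 2-fold or more, 1026 with only the libraries of the compared groups and 193 with the segment covariate. Treated against untreated SHR gave 3590 genes with array weights, and 257 genes then counted as reversed by the drug. Array weights ran from 0.271 to 6.476 over the 9 libraries and called genes in 22 of 60 fits to regrouped libraries, up to 8137 genes, against 1 fit and at most 2 genes for limma without them. Array weights can thus call many genes between sets of the same group make-up. Because group differences enter the spread within regrouped sets, these fits do not measure calibration of either method under the real grouping, and the array-weight counts stay unchecked there. A 2-fold minimum lowers a count by construction, and the segment covariate removes part of any group difference, since the mean levels of its markers differ between the groups; otherwise the cause was not tested. With a library left out, the counts ran from 167 to 626 for SHR against WKY, from 0 to 830 for treated against untreated SHR, from 593 to 4791 for treated SHR against WKY and from 0 to 26 for reversed genes, and the highest value of each came without treated library 1. Lists called ran from 6 to 15 for SHR against WKY, from 6 to 10 for treated against untreated SHR and from 8 to 10 for treated SHR against WKY.

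Camera with an estimated correlation called 0 lists in SHR against WKY, 0 in treated against untreated SHR and 0 in treated SHR against WKY, and fry, which does not compare a list with other genes, called 0, 0 and 10. As deposited, 8 lists were higher and 6 lower in SHR against WKY; with median-of-ratios scaling 8 were higher and 3 lower, and with quantile normalization 8 and 2. Calls of lower lists there thus depend on the scaling. In treated against untreated SHR 7 lists were called with either scaling, 5 and 6 of them among the 7 reported, and in treated SHR against WKY 10 and 9, with 8 and 6 among the 8 reported. With the segment covariate, 8 lists were called in SHR against WKY (14 without it, 7 shared), 9 in treated against untreated SHR (7 without it, 4 shared) and 12 in treated SHR against WKY (8 without it, 4 shared). Under it the median log2 change of glucose carriers in SHR against WKY turned from -0.23 to 0.101, and that of podocyte markers in treated SHR against WKY from 0.88 to -0.012. The podocyte list is 1 of the 2 lists in the covariate, so its change is removed by construction; for glucose carriers the cause was not tested. Of the named genes called, 30 of 50 in SHR against WKY and 33 of 117 in treated SHR against WKY kept their call in all alternatives, and all 50 and all 117 kept their sign. None (0) of the lists called kept its call in all alternatives.

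The replicate numbers do not pair the libraries: of 9 same-numbered pairs, 3 had a correlation of deviations over 0.1 (range -0.328 to 0.456), and 4 of 9 libraries correlated best with their own number. With the replicate block, 282 genes were called in SHR against WKY, 1 in treated against untreated SHR (Slc9a3), 2700 in treated SHR against WKY, and 1 gene, again Slc9a3, counted as reversed. FPKM values without read totals set no limit that can be stated for weakly expressed genes.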

Other observations

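Tests on podocyte levels, on distal minus proximal levels, on early and late proximal genes and on signs among the genes of smallest p were chosen after the results were seen, and the tests on the WKY axis, on neighbouring genes and on other splits before. In treated SHR against WKY, limma called members of several lists not described above. Over all genes 3010 of 13127 were called in that contrast, and the share of clock genes called was near it. Of 23 vasoactive genes 11 rose and 1 fell (13 and 2 adjusted over the list alone), among them Kl, the anti-ageing hormone gene klotho (123 ± 33.5 against 51.1 ± 15.0 FPKM, SD, n = 3), Klk1, tissue kallikrein (2277 ± 983 against 836 ± 242), and Adrb1, the beta-1 adrenoceptor (14.5 ± 1.98 against 5.36 ± 1.68). Of 20 clock genes 3 rose and 2 fell (4 and 3 adjusted over the list alone): Per3 stood at 7.18 ± 1.68 against 2.94 ± 0.756, Dbp at 79.7 ± 19.7 against 35.1 ± 4.83, and Arntl at 8.52 ± 0.997 against 14.4 ± 2.16 FPKM. Of 27 glycolysis and gluconeogenesis genes 10 rose and 4 fell (12 and 5 adjusted over the list alone), with Pkm at 315 ± 63.3 against 165 ± 25.8, Ldha at 237 ± 31.7 against 149 ± 5.62, and Gk, glycerol kinase, lower at 28.3 ± 6.51 against 49.2 ± 6.59. Of 25 cholesterol synthesis genes 9 rose and 1, Lss, fell (11 and 3 adjusted over the list alone), and of 23 hypoxia genes 7 rose (10 adjusted over the list alone). Camera called none (0) of these 5 lists, with a smallest adjusted p of 0.110 for vasoactive genes, and fry, which does not compare a list with other genes, called vasoactive (adjusted p = 0.0476), cholesterol synthesis (0.0282) and hypoxia genes (0.0282). Distal and intercalated markers rose in the same contrast, and these changes were not separated from theirs: with the segment covariate 81 of the 117 named genes called, Kl and Klk1 among them, were no longer called, though that covariate removes part of any group difference.

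Markers of other cells were examined with the same test. In treated SHR against WKY, 3 of 12 podocyte genes rose (9 adjusted over the list alone), and of 13 endothelial genes Ehd3 (42.6 ± 9.98 against 17.4 ± 4.45 FPKM) and Cldn5 (24.3 ± 6.22 against 9.61 ± 3.95) rose while Vwf fell to 1.79 ± 0.971 from 9.19 ± 2.42. Of 9 smooth muscle and pericyte genes 0 passed, of 11 macrophage genes Cd14 rose, of 6 lymphocyte genes Cd79a rose, and of 7 adipocyte genes Fabp4 fell. The neutrophil, adrenal, urothelium and sex-linked lists had under 5 kept genes and were not tested, with S100a9 at 2.02 to 8.50 FPKM, Cyp21a1 at 1.59 to 6.08 and Krt7 at 114 to 281 over the 9 libraries. In SHR against WKY, camera also placed hypoxia (adjusted p = 0.0253), immediate early (0.0186) and vasoactive genes (0.0445) higher and cell cycle genes (0.0419) lower, at adjusted p of 0.806, 0.806, 0.857 and 0.806 with an estimated correlation. As a list, matrix and fibrosis genes were called by camera in no contrast (adjusted p = 0.146, 0.164 and 0.946), nor were tubular injury (0.0637, 0.963 and 0.249), inflammation (0.789, 0.439 and 0.416) or angiotensin and aldosterone genes (0.922, 0.976 and 0.873), although in treated SHR against WKY limma called 3 members higher and 2 lower, 4 and 4, 3 and 4, and 3 and 0 of these lists. Over all genes limma called 3010 of 13127 in that contrast. The list median and the direction of the test differed in sign for 6 lists in SHR against WKY, 3 in treated against untreated SHR and 7 in treated SHR against WKY, and the median and mean for 3, 4 and 4; none of these was a called list.

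Proximal tubule genes were lower and distal genes higher in treated than in untreated SHR, and a different mix of kidney regions in the tissue pieces is a candidate explanation beside the drug. Early and late proximal genes had median log2 changes of -0.842 and -0.879. Treated libraries differed, however: the late mean was above all untreated SHR in treated library 1, and the early mean lay within their range in treated library 2. Region mix alone, as it varies between WKY libraries, predicts a rise of podocyte markers of 1.948 (SE 0.068) on the log2 scale, and the observed rise was 0.107 (SE 0.262). On the linear scale the predicted 0.971 (SE 0.299) and observed 0.106 (SE 0.227) lay closer, the gap just passing 2 standard errors. The prediction rests on a slope through 3 WKY libraries, too few for its standard error to set a limit. That slope was carried from WKY levels of distal minus proximal between -1.57 and -0.86 to treated levels far above them. The test therefore cannot decide on region mix as the whole cause. The change across 65 proximal, distal and intercalated genes correlated at 0.447 with the main axis among WKY libraries, between the bounds fixed beforehand, and at 0.114 to 0.541 with the axis of each WKY pair. Within the 24 proximal genes alone the correlation was -0.414, opposite in sign to what a mix varying as among WKY libraries would give. Another region mix need not give that sign, no bound was fixed for this value and no spread was computed. Region mix, as a part or as the whole of the cause, therefore stays open. All 3 treated libraries exceeded all untreated SHR in distal minus proximal level (0.09, 0.50 and 1.47 against -0.63, -0.56 and -0.32), but the exact permutation p of 0.1 is the smallest this design allows. A drug response and a different region mix therefore cannot be told apart.

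Early proximal transcripts, Slc5a2 among them, varied between libraries of the same group. Slc5a2 differed 7.21 times between the highest and lowest WKY library and 15.9 times among untreated SHR; no biological explanation was tested. A varying share of cortex in the tissue could contribute, and its test, the relation of the early proximal list to podocyte markers within groups, decides neither way (r = 0.368, exact permutation p = 0.333; over all 9 libraries r = -0.234, exact permutation p = 0.554, Spearman's rho = -0.183, exact permutation p = 0.644, and r = -0.217 without the 2 farthest libraries). Late proximal genes instead ran opposite to podocyte markers (r = -0.818, exact permutation p = 0.00908, adjusted p = 0.0272 over 3 relations; rho = -0.933, permutation p = 0.00075; r = -0.747 without the 2 farthest libraries), and within groups r was -0.761 (exact permutation p = 0.0185, adjusted p = 0.0556). The hypothesis that tissue depth shapes the late proximal signal was formed and tested on the same libraries.

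Genes that differed between the strains tended to lie next to each other in the GRCr8 gene order. Pairs that overlap in GRCr8, share a name stem or hold a LOC, RGD or NEWGENE symbol were left out. Of the rest, 19 neighbouring pairs had both genes called, where 10000 random sets of like expression had a median of 8 and a central 95% range that ended at 15, and the genes with the smallest p for treatment gave 8. Of these pairs 13 changed in the same and 6 in opposite directions, among them Clu and Ephx2 with log2 changes of -1.23 and 3.31. Only 10 of 10000 random sets had as many pairs, so pairs caught by these filters are not the whole cause. Overlap was judged on GRCr8 and not on the authors' build, and paralogs by symbol alone, so shared reads may remain. The pair of Setd4 and Cbr1, a gene with close copies nearby, was among the 19. Strain haplotypes that carry several regulatory differences are consistent with this, as a hypothesis, and sequence differences from the reference that alter read mapping were not tested.

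For each contrast the 6 libraries can be split in 10 ways, too few for a share under 0.05. In SHR against WKY 388 genes were called in the real split and at most 1 in another (1 of 10 splits as large), in treated SHR against WKY 3010 and at most 1 (1 of 10), and in treated against untreated SHR 0 and at most 2 (10 of 10). Each other split puts libraries of both groups in each set, so a real group difference enters the spread within sets. Few calls were thus nearly fixed in advance there, and the gap to the real count is no evidence against chance. Lists called were 14 with at most 15 in another split (2 of 10 as many), 7 with at most 13 (9 of 10) and 8 with at most 16 (7 of 10) for SHR against WKY, treated against untreated SHR and treated SHR against WKY.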
